A study of Mus musculus with 12 samples.

How the data were processed

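RNA was measured in dentate gyrus progenitor cells of adult mice in which the transcription factor gene Nfix had been deleted (knockout, KO) or left intact (wild type, WT). The labels name 12 libraries in 4 groups of 3, made with the Smart-seq2 protocol. In one set the cells were marked through a Nestin-CreERT2 driver and taken 60 days after tamoxifen, and the libraries were amplified for 12 cycles. In the other set they were marked through a Dcx-CreERT2 driver, taken 7 days after tamoxifen and amplified for 13 cycles. Nothing in the labels says whether the libraries of a group came from separate animals. P-values of single genes therefore measure only the spread between these libraries, which may be technical. The p-values of gene lists, of overlaps and of counts of genes take genes as units, so they do not measure that spread. Genes that vary together across the libraries can make them too small.

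The values used here come from 2 tables of the authors' own comparisons, KO with WT in each driver set. Per the submitters' processing notes, the genome build was mm10 and the tools named were TopHat, HTSeq and DESeq2, with no versions. The tables carry no header, and their 6 value columns were identified from their values. The authors' deposited base mean is a signal averaged over libraries, in normalised reads per gene, and 1 such mean stands for all libraries of a table. The deposited effect of genotype is a log2 fold change with its standard error (SE). The deposited test score equals the log2 fold change divided by its SE. The deposited p-value is the two-sided normal tail of that score, and the last column is an adjusted p-value that was recomputed here by the Benjamini-Hochberg (BH) method to within 1.2e-05. Values per library were not used here, so the depth of each library is unknown, and no SD between libraries, check of replicates or new fit could be made. Results for single genes therefore keep the p and adjusted p of the authors' deposited tables, with a threshold of 0.05 on the adjusted p, which was the rule fixed for this kind of file before the data were examined.

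Each table lists 23337 gene symbols, of which 25 had been turned into dates by a spreadsheet program and were left out of all tests between tables, of the list tests and of the named genes. Of the genes in the Nestin table, 16025 had a base mean above 0, 14459 had a p and 11959 had an adjusted p. In the Dcx table the numbers were 15142, 13064 and 11109. Genes with a p but no adjusted p lay below a base mean of 68.1 in the Nestin table and 64.3 in the Dcx table. A further 1566 genes in the Nestin table and 2078 in the Dcx table had a log2 fold change but no p, and the reason is not given in the sources used here. Log2 fold changes of low genes were held close to 0. Their SD was 0.14 for genes with a base mean under 10 and 0.41 for well expressed genes in the Nestin table, and 0.19 and 0.42 in the Dcx table, so the values understate the change of low genes.

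Neither table states which genotype is the numerator. Nfix had a log2 fold change of 2.66 in the Nestin table and of -1.70 in the Dcx table as deposited. All values of the Nestin table were therefore multiplied by -1 and those of the Dcx table left as they were, so that a negative value means lower in KO if Nfix is lower in KO. Every direction in the text rests on that choice. Nfix being lower in KO is thus so by construction and is no check of the labels. The direction of one table relative to the other has only a weak check apart from Nfix. The other 5 genes called in both tables moved the same way, as did 57.6% of the 229 genes called in either, while the Spearman correlation over 10728 genes was -0.01.

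The difference between drivers was tested per gene with a two-sided z test of the 2 log2 fold changes over the root of their summed squared SEs, BH adjusted over the 14563 genes with values in both tables. The overlap of calls was tested with a two-sided Fisher's exact test per direction. Before the data were examined, 35 gene lists were fixed, most of them markers of cell types, cell cycle phases and pathways. Of 833 symbols as written or matched by pattern, 831 were found in the tables, 9 of them under an older symbol from the RefSeq table for GRCm38, and 1 list (genes of the mitochondrial genome) found no symbol. Lists were tested with cameraPR of limma 3.58.1 on the signed test score with a preset correlation between genes of 0.01, BH adjusted over the 34 lists within a comparison. A list's members were also counted with p-values adjusted over the list alone. The members of the ribosomal protein and respiratory chain lists were taken by the pattern of their symbols and include a few related proteins.

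The genes named in the text follow a rule set before the data were examined. It takes the 4 nuclear factor I genes, the 10 highest and 10 lowest log2 fold changes among called genes with a base mean of at least 50 and an ordinary gene name, and up to 4 members of each list with the smallest adjusted p. For the difference between drivers it takes 5 genes with the smallest p in each direction, under the same rule on level and name. The rule did not say which table the level refers to, and at least 50 in both tables was required, a reading chosen after the values were seen. Genes named outside the rule are said to have been chosen after their values were seen. Gene positions are RefSeq gene bounds on GRCm38, the assembly also called mm10.

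The z test, the list test and the random lists were tested on simulated data. In the difference between drivers, with the real SEs of 14563 genes and 200 changed genes, 3 of 50 genes with a log2 difference of 1 were recovered, 22 of 50 with 2, 47 of 50 with 3 and 50 of 50 with 4, and 7 unchanged genes were called. For the Nestin gene lists, over 16025 genes and 20 simulated sets, 36 of 40 shifted lists were recovered and 2 of 640 unshifted lists were called. Matched random lists recovered 2 of 2 shifted lists and called 0 of 32 unshifted ones. The simulated scores were drawn independently for each gene. These counts therefore give no rate of false list calls where the members of a list vary together across libraries. Alternatives tried were other thresholds and adjustments, filters on base mean, an empirical null, other list tests and other gene universes. A further 5 gene lists (homeostatic microglia, microglial chemokines, photoreceptor, rod and pineal genes) and some of the alternatives were added after the data had been seen. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.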

Results

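The data describe what deleting Nfix changed in the transcripts of progenitor cells of the adult mouse dentate gyrus. Nfix encodes a transcription factor of the nuclear factor I family. The Nestin set compared 3 KO with 3 WT libraries at 60 days after tamoxifen, in cells marked through a gene active in neural stem cells. The Dcx set compared 3 KO with 3 WT libraries at 7 days, in cells marked through doublecortin, a gene active in neuroblasts. Driver, interval and number of amplification cycles changed together, so a difference between the sets cannot be assigned to one of them. The depth of the libraries is unknown, because the values are the authors' comparison tables.

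Nfix itself was the first gene examined. In the authors' deposited tables its log2 fold change, signed so that it is lower in KO, was -2.66 (SE 0.26, adjusted p = 1.12e-20) in the Nestin set and -1.70 (SE 0.30, adjusted p = 1.15e-05) in the Dcx set. These values correspond to levels 6.34-fold and 3.25-fold lower in KO in the authors' deposited tables. The sign is an assumption, since neither table states its numerator, and every direction given here depends on it, so that Nfix being lower is no check of the labels. The gene lies on chromosome 8 from 84704712 to 84801238 (GRCm38). Whether the counted reads cover the deleted part of the gene is not given in the sources used here. The related genes Nfia, Nfib and Nfic did not pass the threshold in either set. In the Nestin set the authors' deposited table gives them log2 fold changes of 0.47 (adjusted p = 0.433), 0.27 (adjusted p = 0.942) and 0.04 (adjusted p = 0.991). In the Dcx set the authors' deposited table gives -0.23 (adjusted p = 0.999), -0.52 (adjusted p = 0.978) and -0.63 (adjusted p = 0.865). The cameraPR test of the 4-gene family passed in both sets (adjusted p = 0.00932 and 9.4e-05). In the Nestin set its mean was -0.47 while its median was 0.15, and the call rested on Nfix.

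The first comparison asks which genes differed 60 days after deletion in the Nestin lineage. Genes of neural stem cells and radial glia were higher in KO, and genes of microglia were lower. Fabp7, the brain fatty acid binding protein of radial glia, had a log2 fold change of 1.68 (SE 0.19, adjusted p = 7.06e-16) in the authors' deposited table, and Hes5, a Notch effector, 1.60 (SE 0.31, adjusted p = 0.000176). The ephrin receptors Epha3 and Epha5 reached 2.31 (SE 0.26, adjusted p = 3.23e-15) and 2.78 (SE 0.36, adjusted p = 1.65e-11) in the authors' deposited table. Csf1r, the receptor that microglia need to survive, had -1.30 (SE 0.36, adjusted p = 0.0327) in the authors' deposited table and was chosen after its values were seen. Prox1, a homeobox gene of granule neurons, had -1.28 (SE 0.23, adjusted p = 3.33e-05) there. Of 11959 genes with an adjusted p in the authors' deposited table, 153 passed the threshold, 51 higher and 102 lower in KO, and 979 had an unadjusted p under 0.05.

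The 10 largest rises were taken among called genes with a base mean of at least 50 and an ordinary gene name. None of these 10 genes belonged to the neural stem cell and radial glia list. Pde6g (3.83), Rbp3 (3.57), Sag (2.67), Tulp1 (2.38) and Prph2 (2.24), known from photoreceptors, were among them in the authors' deposited table, with adjusted p from 2.37e-13 to 0.000503. Chrnb4, a nicotinic receptor subunit, stood at 3.47 (SE 0.46, adjusted p = 1.2e-10) in the authors' deposited table. Megf11 (2.39) and Odz2 (2.39), a teneurin, completed the set with Epha3 and Epha5 in the authors' deposited table. After Nfix, the largest falls under the same limits in the authors' deposited table were those of the mitochondrial carrier Slc25a45 (-2.33), Sft2d2 (-2.28), N4bp3 (-2.25), the chemokine Ccl2 (-2.19), Sp7 (-2.17), the phosphatase Ptpn6 (-2.17), Mpeg1 (-2.08), the chemokine Ccl12 (-2.04) and Zhx3 (SE 0.38, adjusted p = 0.000104). Pde6g lies on chromosome 11 from 120447607 to 120453500, and Ccl2 on the same chromosome from 82035577 to 82037452 (GRCm38).

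Among the fixed lists, the microglia list moved most in the Nestin set. All 20 members were below 0, with a median of -1.19 and quartiles of -1.25 and -1.12, and 16 passed as lower and 4 did not pass; adjusted over the list alone, 20 were lower. C1qb, C1qc and C1qa, complement genes, had log2 fold changes of -1.13, -1.23 and -1.22 and the lysosomal gene Cd68 -1.39 in the authors' deposited table, with adjusted p between 0.00121 and 0.004. The list passed cameraPR with an adjusted p of 3.13e-42. The immediate early and dissociation stress list was lower as well (adjusted p = 1.49e-10, median -0.42), with 3 members lower, none higher and 20 not past, and 7 lower when adjusted over the list alone. Those 3 were the stress regulator Atf3 (-1.51, adjusted p = 2.23e-05), Junb (-0.90, adjusted p = 0.00456) and the mRNA decay factor Zfp36 (-1.28, adjusted p = 0.0104) in the authors' deposited table. The myelinating oligodendrocyte list was lower as a group (adjusted p = 1.82e-07, median -0.49, 26 of 27 members below 0), although 0 of the 25 members with an adjusted p passed, also when adjusted over the list alone. Tspan2 (-0.78, adjusted p = 0.294) and Trf (-0.60, adjusted p = 0.518) had its smallest adjusted p in the authors' deposited table. The endothelial (median 0.10) and mural cell lists (median 0.02) did not pass (adjusted p = 0.215 and 0.676).

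The neural stem cell and radial glia list was higher in KO (cameraPR adjusted p = 9.48e-11, median 0.49), beside the lower microglia and myelin lists. Of its 24 members with an adjusted p, 4 rose, 0 fell and 20 did not pass; adjusted over the list alone, 6 rose. Besides Fabp7 and Hes5, the risers were Sox9, a transcription factor of glial progenitors (0.86, adjusted p = 0.000608), and Egfr, the epidermal growth factor receptor (1.38, adjusted p = 0.00671), in the authors' deposited table. The axon guidance and adhesion list passed (adjusted p = 0.000311, median 0.13), with 4 risers of 37, 0 falls and 33 not past, and 4 risers adjusted over the list alone. It did not pass a rank-based test (adjusted p = 0.145) or a comparison with matched random lists (adjusted p = 0.103). The semaphorin receptor Nrp1 (1.49, adjusted p = 1.79e-05) and its ligand family member Sema3e (1.54, adjusted p = 0.0281) were among those risers in the authors' deposited table. Of the neuroblast and immature neuron list (adjusted p = 0.0186, median 0.29), the members called did not follow the list. In the authors' deposited table Prox1 and the calcium binding protein gene Calb2 (-1.70, adjusted p = 0.00121) were lower, the transcription factor gene Neurod2 (1.48, adjusted p = 0.00643) was higher, and 23 did not pass; adjusted over the list alone, 2 were higher and 2 lower.

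Further lists passed in the Nestin set through many small values. The S phase list (adjusted p = 0.00138, median 0.30) and the G2 and M phase list (adjusted p = 0.00626, median 0.29) had 22 of 25 and 22 of 26 members above 0, and 0 members of either passed singly or adjusted over the list alone. The nuclear respiratory chain list (adjusted p = 2.17e-05, median 0.18), the cytosolic ribosomal proteins (adjusted p = 0.0479, median 0.13) and the mature neuron and synapse list (adjusted p = 0.0199, median 0.13) likewise had 0 called members, also when adjusted over the list alone. The cholesterol synthesis list (adjusted p = 0.0186, median 0.25) had 0 called members and 1 riser adjusted over the list alone. An estimated correlation could not be had without values per library. With a preset correlation of 0.05 the microglia, stem cell, immediate early, myelin, axon guidance, S phase, respiratory chain and nuclear factor I lists kept an adjusted p at or under 0.0273. At that correlation the adjusted p was 0.067 for G2 and M phase, 0.112 for cholesterol synthesis, 0.13 for neuroblasts, 0.151 for mature neurons and 0.279 for ribosomal proteins.

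The other 21 lists did not pass in the Nestin set, with adjusted p from 0.0607 to 0.723. They were the astrocyte, intermediate progenitor, oligodendrocyte precursor, endothelial, mural, ependymal, interneuron, pyramidal neuron, cell cycle exit, p53 target, apoptosis, cytoskeleton, Notch, BMP, Wnt, Hedgehog, fatty acid, glycolysis, heat shock, interferon and sex-linked lists. Single members of them did pass. The intermediate progenitor list had 2 risers, Elavl2 (1.03, adjusted p = 0.00183) and Hes6 (0.78, adjusted p = 0.0425), and 1 fall, the neurokinin B gene Tac2 (-1.62, adjusted p = 0.0168), in the authors' deposited table. In the same authors' deposited table Ptprz1 of the oligodendrocyte precursor list rose (0.75, adjusted p = 0.00271), as did Itm2a of the endothelial list (1.94, adjusted p = 0.00442) and Fezf2 of the pyramidal list (0.97, adjusted p = 0.000182). Herpud1 of the heat shock and unfolded protein list (-0.67, adjusted p = 0.0117) and the class I gene H2-K1 (-1.20, adjusted p = 0.0203) fell in the authors' deposited table. None of the sex-linked genes with an adjusted p passed in either set (adjusted p of at least 0.897), and 1 of the 5 had none in the Dcx table. Both Xist (base mean 2886) and the Y-linked gene Ddx3y (1196) were expressed in the Nestin set. Without values per library, a balance of the sexes between KO and WT is not shown.

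**Figure D1:**
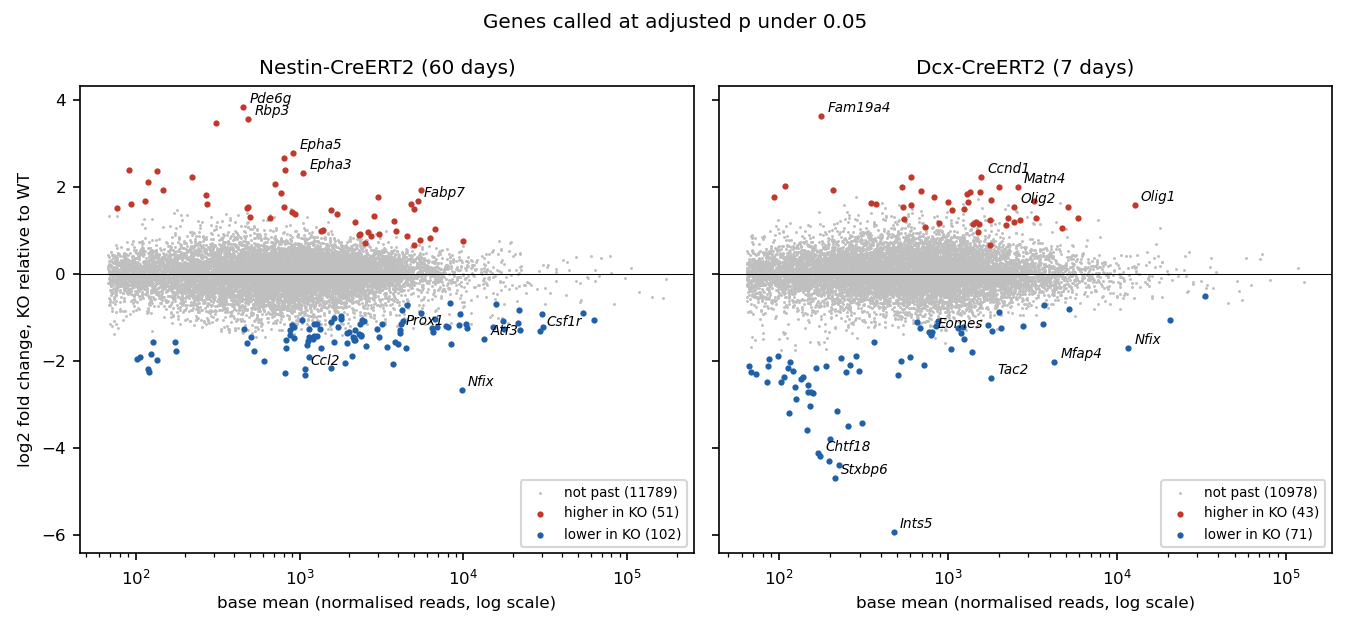
Log2 fold change, KO relative to WT, against base mean (log axis) for the genes with an adjusted p in each of the authors' deposited tables; red points are called higher and blue points called lower in KO. Of the 71 genes called lower in the Dcx set, 41 have a base mean under 500, against 11 of 102 in the Nestin set.

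The second comparison asks the same question 7 days after deletion in the Dcx lineage. Genes of oligodendrocyte precursors were higher in KO, and 3 genes of intermediate progenitors were lower. The oligodendrocyte lineage factors Olig1 and Olig2 had log2 fold changes of 1.58 (SE 0.38, adjusted p = 0.00599) and 1.54 (SE 0.34, adjusted p = 0.00158) in the authors' deposited table. Mfap4, a microfibril protein gene, had -2.02 (SE 0.30, adjusted p = 1.87e-08) and Eomes, the T-box factor of intermediate progenitors, -1.33 (SE 0.35, adjusted p = 0.021) in the authors' deposited table. Ccnd1, which encodes cyclin D1, reached 2.23 (SE 0.36, adjusted p = 4.82e-07) there. Of 11109 genes with an adjusted p in the authors' deposited table, 114 passed, 43 higher and 71 lower in KO, and 776 had an unadjusted p under 0.05.

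The largest rises under the same limits in the authors' deposited table were those of Fam19a4 (3.63), a secreted chemokine-like protein, Ccnd1, Zcchc24 (2.22), Gt(ROSA)26Sor (2.01), the matrilin gene Matn4 (2.00), Lhfpl3 (2.00), Tmtc2 (1.94), the unconventional myosin gene Myo10 (1.91), the endothelin receptor gene Ednrb (1.89) and pleiotrophin, Ptn (1.88). The largest falls under these limits were larger and concerned genes with a base mean under 500. Ints5, an Integrator subunit, had -5.94 (SE 0.45, adjusted p = 4.4e-36) at a base mean of 476 in the authors' deposited table. Stxbp6 (-4.69), Chtf18 (-4.18), Zfp458 (-4.13), Xkr8 (-3.80), the mitochondrial alanyl-tRNA synthetase gene Aars2 (-3.49), Rmnd5a (-3.42), Setmar (-3.20), the DNA repair gene Brca2 (-3.16) and Dus4l (-3.04) followed in the authors' deposited table, at base means between 115 and 310. Of the 71 genes that were lower, 41 had a base mean under 500, against 6 of the 43 that were higher. Among genes with a base mean of at least 500, an analysis chosen after seeing the data, 67 passed, 37 higher and 30 lower. Ints5 lies on chromosome 19 from 8892987 to 8897890 (GRCm38).

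The oligodendrocyte precursor list had the smallest adjusted p in the Dcx set (cameraPR adjusted p = 4.6e-20, median 0.90). All 23 members were above 0, 6 of 21 with an adjusted p rose, 0 fell and 15 did not pass; adjusted over the list alone, 10 rose. Olig2, Olig1, Matn4 and Lhfpl3 were its leading members. The astrocyte list also passed (adjusted p = 0.00178, median 0.25), with 1 riser, 0 falls and 20 not past, and 2 risers adjusted over the list alone, and an adjusted p of 0.051 against matched random lists. That riser was the glutamate transporter gene Slc1a3 (1.05, adjusted p = 0.00465) in the authors' deposited table. The myelinating oligodendrocyte (median 0.05) and microglia lists (median 0.11) did not pass (adjusted p = 0.798 and 0.634). The neural stem cell list did not pass either (adjusted p = 0.0585), although Ednrb and Fabp7 (1.25, adjusted p = 0.0263) rose in the authors' deposited table; adjusted over the list alone, 3 rose.

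The intermediate progenitor list was lower in KO (adjusted p = 9.39e-06, median -0.23), with 3 members lower, 0 higher and 13 not past, and 4 lower adjusted over the list alone. Against matched random lists it did not pass (adjusted p = 0.136). Beside Mfap4 and Eomes the member that fell was Tac2, with -2.40 (SE 0.43, adjusted p = 1.15e-05) in the authors' deposited table. The neuroblast and immature neuron list was lower as a group (adjusted p = 0.00178, median -0.28, 19 of 27 members below 0), with 0 of 26 members past the threshold, also when adjusted over the list alone. Calb2 (-0.97, adjusted p = 0.469) and the proneural gene Neurod1 (-0.80, adjusted p = 0.479) had the smallest adjusted p of that list in the authors' deposited table. The ependymal and choroid plexus list passed narrowly (adjusted p = 0.0481, median -0.22) with 0 of 3 members called, also when adjusted over the list alone. With a correlation of 0.05 its adjusted p was 0.127, and those of the oligodendrocyte precursor, intermediate progenitor, nuclear factor I, astrocyte and neuroblast lists stayed at or under 0.0468. An estimated correlation was again not to be had. The other 28 lists had adjusted p of at least 0.0585, among them S phase (0.219), G2 and M phase (0.475) and cholesterol synthesis (0.0753). Dkk3, a secreted protein gene in the pyramidal neuron and Wnt lists, fell (-1.71, adjusted p = 0.00401) in the authors' deposited table.

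**Figure D2:**
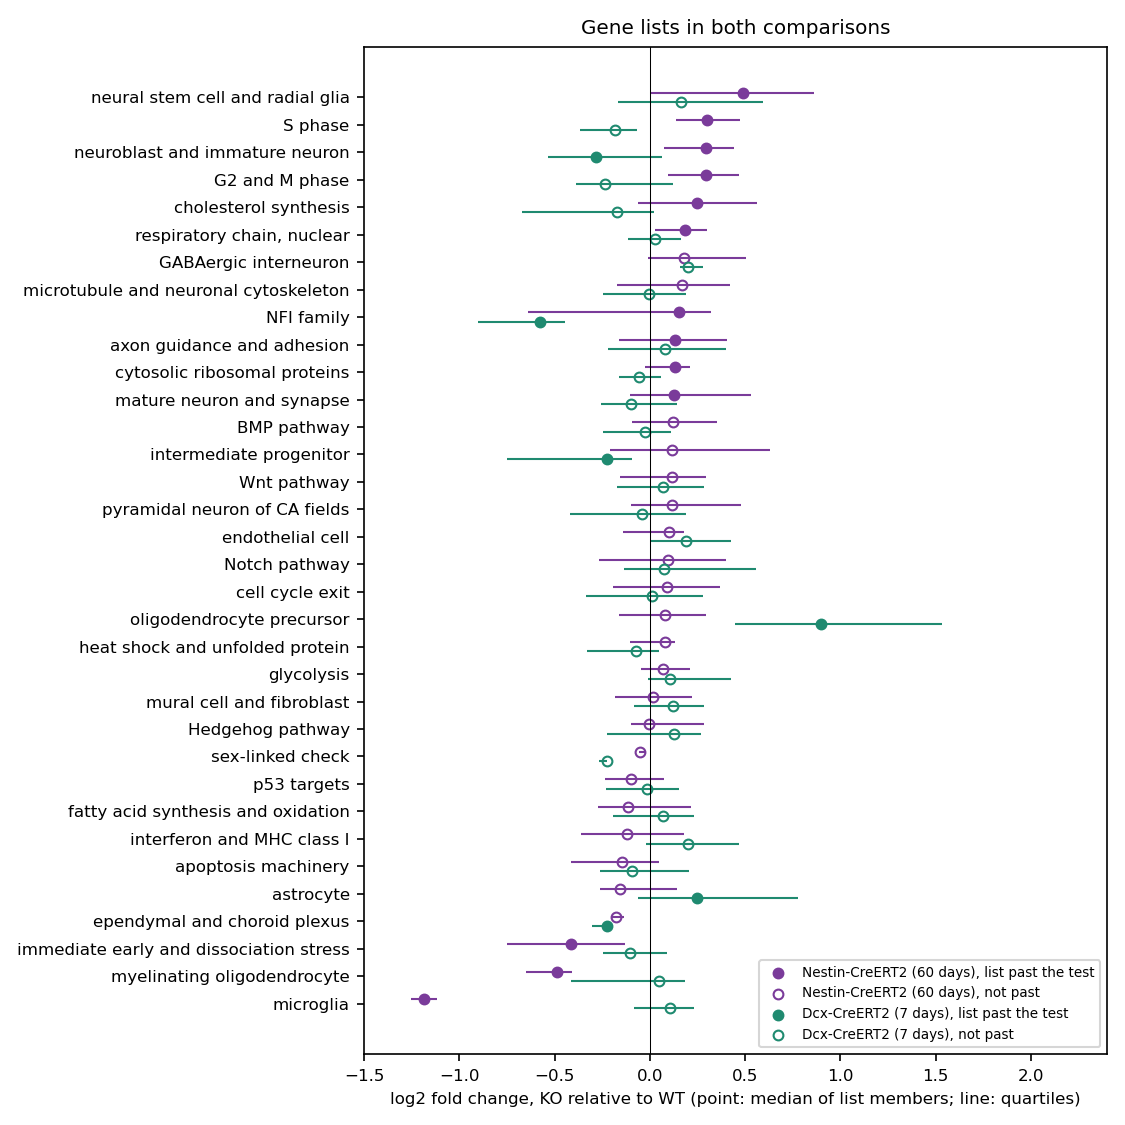
Median log2 fold change, KO relative to WT, of each fixed gene list (points, filled where cameraPR passed the threshold) with the quartiles of its members (lines) in the Nestin and Dcx sets. The microglia list stands at -1.19 in the Nestin set and the oligodendrocyte precursor list at 0.90 in the Dcx set.

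The third comparison asks whether the effect of Nfix deletion differed between the driver sets. By the z test, 59 of 14563 genes differed, 37 with a higher value in the Nestin set and 22 with a lower one. Genes with a base mean of at least 50 in both tables and an ordinary gene name were ranked by p. The 5 smallest p in the first direction belonged to Ints5, Chtf18, Zfp458, Stxbp6 and Xkr8. These genes fell in the Dcx set and had a base mean under 500 there. Ints5, for example, had -0.37 (SE 0.43) in the Nestin set and -5.94 (SE 0.45) in the Dcx set of the authors' deposited tables, a difference of 5.56 (SE 0.62, adjusted p = 3.72e-15). In the other direction Ccnd1 had -0.69 (SE 0.37) in the Nestin set and 2.23 in the Dcx set of the authors' deposited tables, a difference of -2.92 (SE 0.52, adjusted p = 1.55e-05). Sft2d2 (-2.47, adjusted p = 0.00172), Tmem64 (-2.85, adjusted p = 0.00274), the protease inhibitor gene Serpine2 (-2.27, adjusted p = 0.00751) and the sialyltransferase gene St3gal6 (-2.64, adjusted p = 0.00751) followed by size of p under the same limits. Some genes outside these limits had p as small, among them Pde6g, Rbp3 and Chrnb4, named after their values were seen. Their base means in the Dcx set of the authors' deposited tables were 11.9, 3.90 and 0.117, so the z test does not show that the effect of genotype differed for them. Tmem64 had no p in the Nestin table, and 9 of the 59 genes lacked a p in at least 1 table.

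Gene groups differed between the sets as well. Compared with the Dcx set, the Nestin set had lower values for the microglia list (cameraPR adjusted p = 2.47e-15), the oligodendrocyte precursor list (adjusted p = 1.64e-09), the myelinating oligodendrocyte list (adjusted p = 0.00143) and the astrocyte list (adjusted p = 0.00285). It had higher values for the neuroblast list (adjusted p = 4.19e-05), the intermediate progenitor list (adjusted p = 8.92e-05), the S phase list (adjusted p = 0.00143) and the cholesterol synthesis list (adjusted p = 0.00228). The neuroblast list had medians of 0.29 and -0.28 and the S phase list 0.30 and -0.18 in the Nestin and Dcx sets. These 8 lists kept an adjusted p at or under 0.0452 with a correlation of 0.05. A further 7 lists passed at 0.01 and not at 0.05, where their adjusted p lay between 0.105 and 0.273. The neural stem cell list did not differ by this test (adjusted p = 0.0988). Members of the oligodendrocyte precursor list had a median base mean of 307 in the Nestin set and 2018 in the Dcx set, normalised separately. Log2 fold changes of low genes are held close to 0. For this list the test therefore does not separate a different effect of genotype from a difference in level.

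The last comparison asks whether the sets shared genes. Among 10728 genes with an adjusted p in both tables, 6 were called in both, each in the same direction. Fabp7 and Ptprz1 were higher in KO, against 0.135 expected (Fisher's exact test, p = 0.00792), and Nfix, Tac2, Mxd1 and Scoc were lower, against 0.578 expected (p = 0.00263). Nfix, the deleted gene, was lower in both by the choice of sign, so its place there is no evidence of overlap. Without Nfix, 3 shared genes were lower, against 0.564 expected (Fisher's exact test, p = 0.0187). Mxd1, a MYC network repressor gene, had -1.22 (SE 0.29) in the Nestin and -2.10 (SE 0.43) in the Dcx set of the authors' deposited tables. Scoc, a gene of autophagy regulation, had -1.05 (SE 0.30) and -1.24 (SE 0.35), and Ptprz1, a receptor phosphatase of glial progenitors, 0.75 (SE 0.17) and 1.53 (SE 0.40) in the authors' deposited tables. These genes were named because the count is small, after their values were seen. Scoc lies on chromosome 8 from 83434492 to 83458436, near Nfix (84704712 to 84801238, GRCm38). Junb, called lower in the Nestin set, also lies near Nfix, from 84976909 to 84978748. Whether their lower values are linked to that position was not tested. Leaving out Nfix, 132 of 229 genes called in either set had the same sign in both (57.6%, exact binomial 95% interval 51% to 64.1%). Across all 10728 genes, which are not independent replicates, the Spearman correlation of the log2 fold changes was -0.01.

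**Figure D3:**
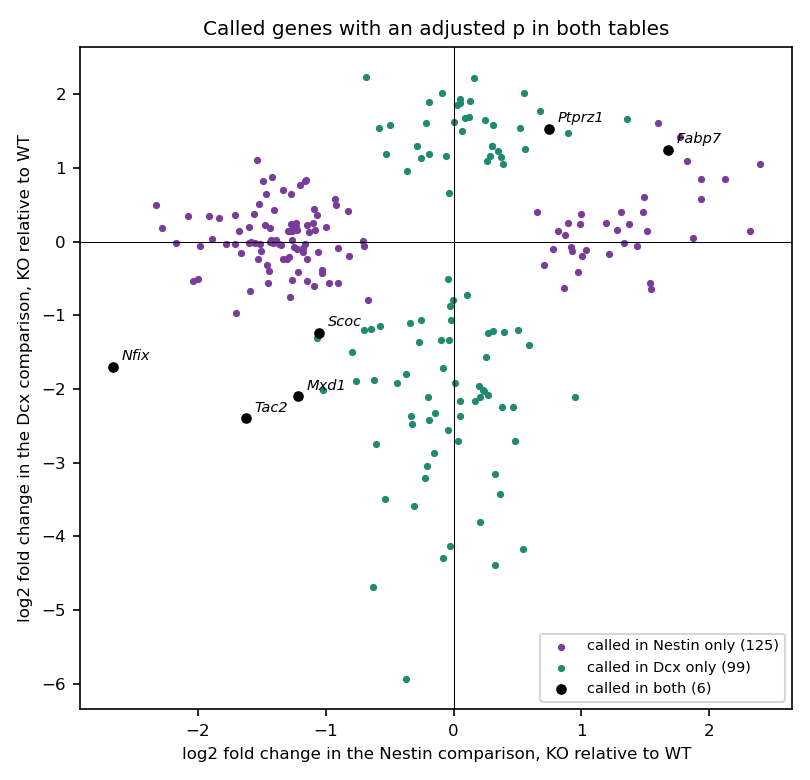
Log2 fold changes, KO relative to WT, in the Nestin set (horizontal) and the Dcx set (vertical) for genes called in either of the authors' deposited tables with an adjusted p in both. The 6 genes called in both (black) lie where both values have the same sign, Nfix by the choice of sign.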

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

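The tests of the microglial pattern and the test of the sides of the weak Dcx calls were chosen after the results were seen. The tests for retinal RNA, pineal RNA and dropout were set before, except that the count of pineal genes above 0 was added after. Values that differed between the driver sets by the z test of the difference come first. By that test 59 genes passed, of which 9 lack a p in at least 1 table, and 49 passed among genes with a p in both tables. The adjusted p was 3.72e-15 for Ints5, 1.1e-08 for Chtf18, 1.95e-08 for Zfp458, 5.06e-07 for Stxbp6 and 2.73e-06 for Xkr8, all with lower values in the Dcx set. It was 1.55e-05 for Ccnd1, 0.00172 for Sft2d2, 0.00274 for Tmem64, and 0.00751 for Serpine2 and for St3gal6, all with lower values in the Nestin set. Lists with lower values in the Nestin set were microglia (adjusted p = 2.47e-15), oligodendrocyte precursor (1.64e-09), myelinating oligodendrocyte (0.00143), astrocyte (0.00285), immediate early and dissociation stress (0.0143), and interferon and MHC class I (0.0442). Lists with higher values there were neuroblast (4.19e-05), intermediate progenitor (8.92e-05), S phase (0.00143), cholesterol synthesis (0.00228), G2 and M phase (0.0121), respiratory chain (0.0143), ribosomal proteins (0.028), and mature neuron and pyramidal neuron (both 0.0442). With a correlation of 0.05 the adjusted p was 0.118 for immediate early, 0.153 for interferon, 0.105 for G2 and M phase, 0.229 for respiratory chain, 0.273 for ribosomal proteins, 0.229 for mature neuron and 0.135 for pyramidal neuron. In the rank-based test interferon (0.14), mature neuron (0.0763) and pyramidal neuron (0.228) did not pass either. Many oligodendrocyte precursor genes were low in the Nestin set, so for that list a difference in level is not separated from a different effect of genotype.

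Microglial genes were lower in the Nestin KO group, and they are abundant: Csf1r and C1qb ranked 39 and 58 of all genes by base mean, although the labels call the cells progenitors marked by a reporter. All 20 members of the microglia list with a p were lower (100%), with an upper quartile of -1.12; the same genes made the pattern, so this does not test a lower share of microglial RNA in the KO libraries. A lower share of every other cell type alike is argued against, since the microglia median lay -0.70 (95% bootstrap interval over genes -0.80 to -0.54) from the myelinating oligodendrocyte median. Homeostatic microglial genes had a median of -1.19 with an upper quartile of -1.08. A lower share and a loss of the homeostatic state would both give such a median. Of these 12 genes 11 were below 0, and Sall1 stood at 0.04 (p = 0.877) in the authors' deposited table. A lower share of microglial RNA, from the sort or from the tissue, and a change of microglial state both stay open, as does an effect of Nfix deletion, which was not tested.

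Among the genes called higher in the Nestin KO group, 7 are known from photoreceptors (Pde6g, Rbp3, Sag, Tulp1, Prph2, Aipl1 and Rom1), picked because they were called, so their number tests nothing. RNA of retinal tissue is argued against, since 0 of 16 other rod genes passed an unadjusted p of 0.05 as higher in KO at a base mean of at least 10, and 8 of the 16 are listed at 0. Of 12 pineal genes, 0 met the same rule, which by the bound set before argues against pineal RNA, and the members at levels like those of the called genes rose little in the authors' deposited table: Gnb3 (0.43, p = 0.174), Rorb (0.61, p = 0.0761), Crx (0.53, p = 0.115) and Chrna3 (0.23, p = 0.403). That bound was set wrongly, as the list left out the called genes. The list's median base mean was 34.3, where log2 fold changes are held near 0. All 11 members with a value were above 0 (exact binomial p = 0.00034 against 48.4% of genes of like level). The binomial test takes genes measured in the same libraries as independent, which they are not, so no conclusion is drawn from its p. Pineal RNA in 1 or more KO libraries therefore stays open, as does a response of the cells to Nfix loss, which was not tested.

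Genes called lower in the Dcx KO group mostly had a low base mean. That mean averages KO and WT libraries, so a large fall in KO itself lowers it. Of 71 such genes, 41 had a base mean under 500, as did 4737 of the 11109 genes with an adjusted p. Of 47 calls with a base mean under 500, 41 were lower (87.2%, exact binomial 95% interval 74.3% to 95.2%). The pattern was seen in these same counts, and genes measured in the same libraries are not independent. The interval therefore does not test a wider spread of weak genes in either direction. Lower depth or more dropout in the KO libraries was predicted to shift all weak genes down, and their median lay 0.033 (95% bootstrap interval 0.0053 to 0.0578) above that of the most abundant genes, so no such shift was seen. The bound set before was wrong as a test of dropout, since the 41 genes are too few among 4737 weak genes to move a median. A wider spread of weak genes and loss of single transcripts stay open, as does an effect of Nfix deletion, which was not tested.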

How the results depend on the processing

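The settings that use genes with a base mean of at least 500, genes with a p in both tables, lists over genes with a p, calls without Nfix and calls without the microglia list were chosen after seeing the data. Without the microglia list 135 genes passed in the Nestin set, and among genes with a base mean of at least 500 there were 142, of which 126 were among the 153. The counts of called genes changed by over 1.5 times under stricter rules, as their construction requires. At a threshold of 0.01 they were 85 (Nestin) and 68 (Dcx), by the Benjamini-Yekutieli adjustment 64 and 60, and by Bonferroni 39 and 38. Among genes with a base mean of at least 500 the Dcx count was 67, with 44.8% lower in KO against 62.3%. Under the other settings the counts ranged from 130 to 208 (Nestin) and from 108 to 145 (Dcx). At a threshold of 0.1 the genes that differed between drivers numbered 100, and 49 to 58 under the other settings. The overlap of calls stayed past its threshold in both directions (p from 0.000244 to 0.0243), also without Nfix. The Nfix values moved by at most 0.02 after centring.

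With a correlation of 0.05 the lists past the threshold numbered 8 (Nestin, main 13), 5 (Dcx, main 6) and 8 (difference, main 15). Against matched random lists 3 lists passed in the Dcx set, and the intermediate progenitor, ependymal (adjusted p = 0.136 for both) and astrocyte lists (0.051) did not. The ependymal list also did not pass over genes with a base mean of at least 10 (0.0596) or with a p (0.128). The nuclear factor I list of the Nestin set changed sign in the rank-based test (adjusted p = 0.535) and against random lists (0.478), since only Nfix was lower among its 4 genes. The axon guidance (0.145 and 0.103) and mature neuron lists (0.0632 and 0.103) did not pass there in either. Cholesterol synthesis did not pass in the rank-based test (0.0522), nor ribosomal proteins over genes with a base mean of at least 10 (0.0653) or with a p (0.0538). Some lists passed only under an alternative. The Nestin pyramidal neuron list passed over genes with a base mean of at least 10 (adjusted p = 0.0187) or with a p (0.0328). The Nestin interneuron list passed against matched random lists (0.0377), and the Dcx neural stem cell list over genes with a p (0.0469). The causes of the other changes were not tested.

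No paired analysis was possible because the groups share no replicate numbers in the labels and values per library were not used. For the same reason other size factors, another count test, leaving out each replicate, another pseudocount and other splits of the samples were not run, and chance was not examined in that way. Depth is unknown, and the smallest log2 fold change called was 0.66 in the Nestin set and 0.50 in the Dcx set.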

Other observations

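Both sets held abundant oligodendrocyte RNA. Mbp, the myelin basic protein gene, ranked 20 by base mean in the Nestin table and 7 in the Dcx table. In contrast, the precursor genes Pdgfra and Cspg4 had base means of 44.9 and 153 in the Nestin table and 4581 and 1505 in the Dcx table. The tables were normalised separately, so these levels are compared by rank within a table: Pdgfra ranked 12669 in the first and 369 in the second.

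Chemokine genes were among the microglial genes that were lower in the Nestin KO group. Of 10 chemokine and cytokine genes looked up after the calls were seen, 4 passed (Ccl2, Ccl12, Ccl3 and Ccl4), and all 10 had log2 fold changes below 0, with a median of -0.89. In the Dcx set 0 of them passed, and their median was -0.04. Further genes known from the retina or the pineal gland rose in the Nestin KO group in the authors' deposited table, and both were chosen after their values were seen: Tph1, which encodes the first enzyme of peripheral serotonin synthesis (2.08), and Rlbp1, a retinaldehyde binding protein gene (1.77). Rlbp1 also had a base mean of 2559 and a log2 fold change of 1.43 (adjusted p = 0.114) in the Dcx set of the authors' deposited tables. In the Dcx table Sag, Tulp1 and Prph2 are listed at 0.

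The Gt(ROSA)26Sor locus, a common insertion site of reporter alleles, had log2 fold changes of 2.01 (SE 0.45, adjusted p = 0.00205) in the Dcx set and 0.55 (SE 0.39, adjusted p = 0.818) in the Nestin set of the authors' deposited tables. The difference between the sets was not among the 59 genes past the threshold.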
